A study of Mus musculus with 20 samples.

How the data were processed

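Messenger RNA was sequenced from dissociated mouse hippocampal cultures in 4 groups of 5 libraries. Per the labels' protocols, the tissue came from C57BL6 embryos at embryonic day 18, was pooled from 4 embryos, and was grown in Neurobasal medium with B27 supplement, with 4 µM cytosine arabinoside (a drug that kills dividing cells) from day 3 to day 6. At day 10 in vitro the cultures were stimulated for 2 min and returned to 37 °C for 90 min before lysis. Polyadenylated RNA was turned into stranded libraries, per the labels. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.3.1, featureCounts, R 3.3.0, DESeq2 1.14.1 and the mouse build mm10. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be shared.

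The authors deposited a table of whole-number gene counts for 24419 genes in 20 libraries, and these counts were the only values that entered a test here. A second deposited table holds TPM, which the authors obtained by dividing the counts by gene length and rescaling each library. The deposited annotation gives each gene's length in bases and its mm10 position. In 6 tables of the authors' own comparisons, the deposited columns are a mean normalized signal per gene, a shrunken log2 fold change with its standard error, a test score (the Wald statistic), and a p-value with its adjusted p-value. Some gene symbols in the TPM table and in 5 of the comparison tables had been turned into dates by a spreadsheet, so symbols were taken from the counts table. Fold changes in those tables are named below as coming from the authors' deposited table and were not mixed with those computed here.

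Library totals ran from 28692470 to 40934630 counts. A count of 3 corresponded to 0.105 CPM (counts scaled to a common library size) in the smallest library and 0.0733 CPM in the largest, which covers counting error only. Genes were kept by edgeR's default expression filter, which left 14411 genes holding 99.98% of all counts. The mitochondrially encoded list had no members among the genes counted, and no blood marker passed the filter. Counts were scaled by TMM factors, and log2 CPM values used a prior count of 2.

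Every comparison was a contrast in a single edgeR 4.0.16 quasi-likelihood model of all 20 libraries with 4 group means and no covariate (R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicate numbers in the labels were not used as a block. For fixed gene lists, counts of members past the threshold are given over all genes and adjusted over the list alone. The 33 lists were also tested with limma 3.58.1's camera at a preset correlation of 0.01 between genes, again with the correlation estimated, and with fry. Of these lists, 31 had at least 3 tested members. Library totals, the share of counts in the 10 most abundant genes, and marker, ribosomal, oxidative phosphorylation, nuclear RNA and histone list means were compared between groups by 2-sided exact permutation tests, a family of 96. In this text "rose", "fell" and "changed" are used of genes past the adjusted threshold.

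The genes named in the text follow a rule set before the data were examined, as were the lists, the tests and the other settings to be tried. In each comparison the rule takes up to 10 genes with the largest rise and up to 10 with the largest fall past the threshold, with a mean of at least 1 CPM and an established symbol, or the 3 smallest p-values where none passed. It adds 10 fixed genes (Fos, Egr1, Arc, Npas4, Nr4a1, Bdnf, Mt1, Mt2, Slc30a1, Slc39a10) and up to 4 list members with the smallest p-values. Names outside the rule are marked as chosen after their values were seen. A gene that the rule takes for zinc against glutamate is not reported here.

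The model was tested on simulated counts for all 14411 genes with 200 genes changed. Each count was drawn independently with its gene's own spread. No deviation shared across a library and no GC trend was put in, so the rates may not hold for the real libraries. In the simulated comparison of glutamate with control it recovered 55.2% of genes changed 1.25-fold, 88.1% of those changed 1.5-fold and 86.4% of those changed 2-fold, and 3.77% of the calls were false. For zinc against glutamate the recovery in the same order was 52.2%, 80.6% and 89.4% with 2.63% false calls. For TPA against glutamate it was 55.2%, 83.6% and 89.4% with 5.0% false calls, and for TPA against zinc 58.2%, 74.6% and 89.4% with 4.52% false calls.

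Other settings chosen in advance were DESeq2's size factors in edgeR, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum mean of 1 CPM, a fit of the 2 groups alone, the replicate number as a block, and each library left out in turn. Added after seeing the data were a within-library loess offset on transcript GC content (span 0.5), the same with the block, library weights in limma-voom, and fits without 3 libraries. The 3 were taken by 2 routes, by a distance rule and by eye from a principal component plot. For each comparison, 100 splits of the 10 libraries involved into 5 and 5 were refitted.

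The zinc and TPA contrasts share the glutamate libraries, so their correlation was set beside 100 draws of unchanged groups and beside fits with the glutamate libraries split. Genes of the glutamate response were chosen with 3 of the 5 glutamate libraries and read in the remaining 2.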

Results

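Cultured hippocampal neurons from embryonic mice were given a 2-min pulse of medium alone (control), of 50 µM glutamate, of 50 µM glutamate with 10 µM ZnCl2, or of 50 µM glutamate with 10 µM TPA (tris(2-pyridylmethyl)amine, a chelator of zinc ions) after 1 min of preincubation with the chelator. RNA was taken 90 min later, with 5 libraries per group. None of the groups analysed here received zinc or TPA without glutamate. The comparisons ask which transcripts respond to a brief glutamate stimulus and how that response depends on the zinc present during it. Library totals were 36106575 to 39765787 counts in control, 35559330 to 40934630 in glutamate, 33445137 to 38435627 with zinc and 28692470 to 38767979 with TPA. The labels call the 5 libraries of a group biological replicates, but with tissue pooled from 4 embryos the p-values measure only the spread between these samples. Values are CPM as mean ± SD with n = 5, and log2 fold changes carry their standard error (SE).

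Glutamate raised a small set of early response genes. Klf4, which encodes a zinc-finger transcription factor, was 2.94-fold higher than in control (2.11 ± 0.507 against 0.715 ± 0.132 CPM, n = 5 each; log2 fold change 1.56, SE 0.18, edgeR adjusted p = 0.000102). Fosb, a subunit of the AP-1 transcription factor, was 2.32-fold higher (18.7 ± 3.07 against 8.05 ± 0.693 CPM; log2 fold change 1.22, SE 0.12, adjusted p = 1.31e-05). Nfkbiz, a nuclear member of the IκB family, was 1.53-fold higher (2.50 ± 0.136 against 1.63 ± 0.119 CPM; log2 fold change 0.62, SE 0.10, adjusted p = 0.0097). For each of these genes all 5 glutamate libraries lay above all 5 control libraries. Their mm10 positions are chromosome 4, 55527137 to 55532475 for Klf4, chromosome 7, 19302696 to 19310045 for Fosb, and chromosome 16, 55811377 to 55838641 for Nfkbiz.

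Of the 23 tested rapid immediate early genes, 21 had a positive fold change after glutamate, with a median log2 fold change of 0.39. Over all genes 2 of them rose (Klf4 and Fosb), and adjusted over the list alone 17 rose. As a set the list was higher than other genes (camera adjusted p = 6.37e-29), and it stayed past the threshold with adjusted p = 0.00648 with an estimated correlation. Fos, the founding AP-1 subunit, had 76.0 ± 19.3 CPM against 35.1 ± 4.32 in control (log2 fold change 1.12, SE 0.19, adjusted p = 0.0502). Npas4, an activity-dependent transcription factor of neurons, had a log2 fold change of 0.84 (SE 0.16, adjusted p = 0.152). For Egr1, a zinc-finger transcription factor, it was 0.39 (SE 0.11, adjusted p = 0.779). Arc, which encodes a synaptic cytoskeletal protein, had 0.34 (SE 0.12), and Nr4a1, an orphan nuclear receptor, 0.57 (SE 0.19), neither past the threshold over all genes. Fos (adjusted p = 0.00103) and Npas4 (0.0237) passed in the authors' deposited DESeq2 table, while Egr1, Arc and Nr4a1 did not.

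Other lists moved less after glutamate. Among 31 delayed activity-regulated genes 30 had positive fold changes (median 0.14), none rose over all genes, and 3 rose adjusted over the list alone, namely Gadd45g (0.42, SE 0.13), the kinase gene Sik1 (0.18, SE 0.04) and Trib1 (0.32, SE 0.10). That list's camera adjusted p was 1.76e-06, and adjusted p = 0.733 with an estimated correlation. The heat shock and unfolded protein response list (16 of 23 positive, median 0.14, camera adjusted p = 0.00405) had 0 members past the threshold over all genes and 0 adjusted over the list alone, with Creld2 at 0.31 (SE 0.14) and the endoplasmic reticulum disulfide isomerase Pdia4 at 0.19 (SE 0.09). Lower medians were measured for GABA receptors (-0.06, 13 of 14 negative, camera adjusted p = 0.0112), clustered protocadherins (-0.06, 46 of 56 negative, 0.000875), cytosolic ribosomal proteins (-0.03, 70 of 82 negative, 0.000256) and nuclear oxidative phosphorylation genes (-0.03, 67 of 88 negative, 0.00351). Glutamate replicate 4 was the lowest library of its group for GABA receptors and protocadherins, and without it their medians were -0.033 and -0.014 (camera adjusted p = 0.201 and 0.488). The heat shock list lost its call without glutamate replicate 4 (median 0.091) or 2 (0.11), and the oxidative phosphorylation list without control replicate 2 (-0.013) or 4 (-0.012). Without glutamate replicate 3 the ribosomal and oxidative phosphorylation medians turned to 0.017 and 0.0042. The median of the delayed genes was 0.22 without glutamate replicate 5, their lowest library, and 0.084 without glutamate replicate 2. Examples were Gabra3 at -0.17 (SE 0.06) and Pcdha10 at -0.26 (SE 0.08). For these 5 lists adjusted p = 0.733 with an estimated correlation. Bdnf, the neurotrophin gene, had a log2 fold change of 0.17 (SE 0.13), which was 0.29 without glutamate replicate 5, its lowest library, and 0.11 without glutamate replicate 4. The zinc-binding metallothioneins Mt1 and Mt2 had 0.07 (SE 0.06) and 0.17 (SE 0.08), the zinc exporter gene Slc30a1 0.08 (SE 0.06) and the zinc importer gene Slc39a10 -0.13 (SE 0.06), none past the threshold.

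In all, 3 genes rose and 0 fell in edgeR, with 717 genes at an unadjusted p under 0.05 where 721 are expected by chance. limma-voom called 4 genes and DESeq2 14, and the authors' deposited table lists 11 at the same threshold, among them all 3 found here. The count was 5 without glutamate replicate 4, 5 with DESeq2's size factors or with a minimum mean of 1 CPM, 100 without the 3 libraries farthest from their group means, 5 without 3 libraries picked by eye, and 59 with library weights in limma-voom, the last 3 being choices made after seeing the data.

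**Figure D1:**
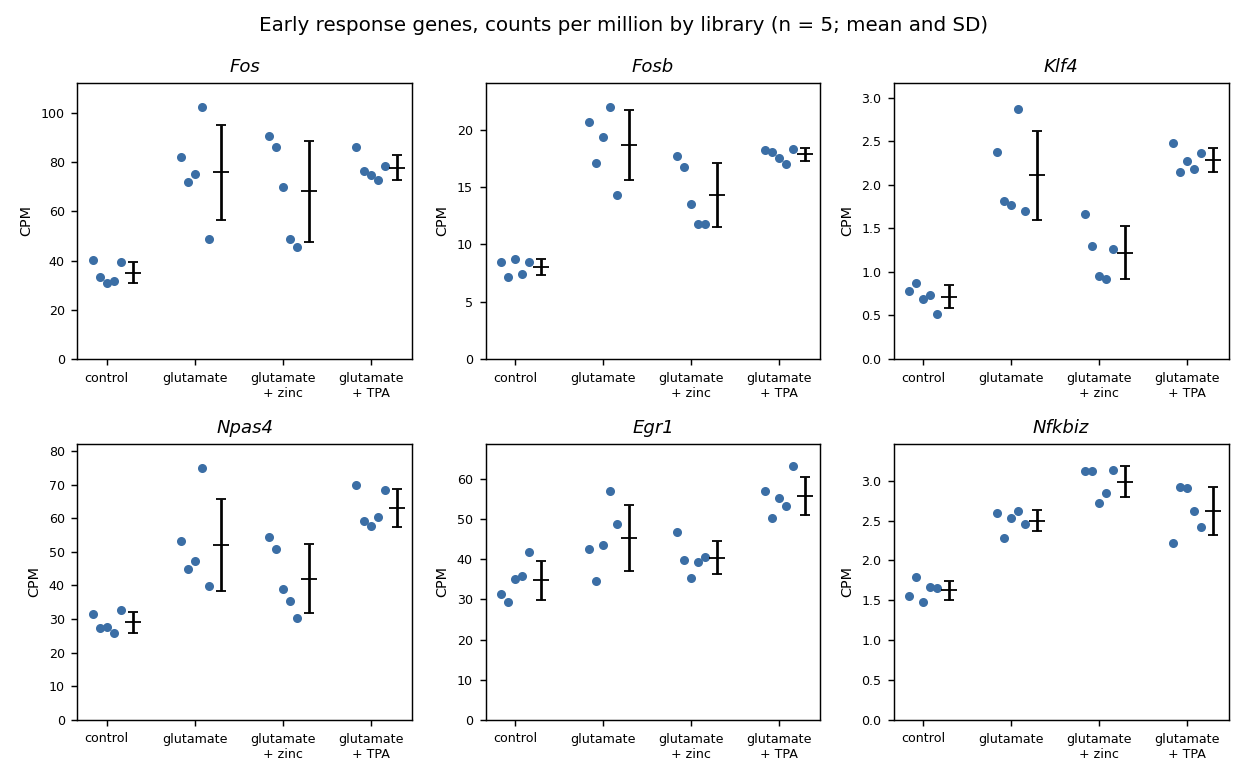
CPM of Fos, Fosb, Klf4, Npas4, Egr1 and Nfkbiz in each library of the 4 groups (points, n = 5 per group), with the mean and SD as a bar. Klf4 averaged 0.715 CPM in control and 2.11 CPM after glutamate, 1.22 CPM with added zinc and 2.29 CPM with TPA.

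With zinc added to the glutamate pulse, no gene passed the threshold against glutamate alone. Small p-values belonged to Klf4, at 1.22 ± 0.304 CPM with zinc and 2.11 ± 0.507 without (n = 5 each; log2 fold change -0.79, SE 0.17, adjusted p = 0.585), and to Icmt, a protein methyltransferase gene, at 44.8 ± 1.81 against 50.2 ± 1.04 CPM (-0.16, SE 0.04, adjusted p = 0.585). Of the 23 rapid immediate early genes 17 had negative fold changes (median -0.12). Over all genes 0 fell, and adjusted over the list alone 3 fell, namely Klf4, Fosb (-0.38, SE 0.11) and Btg2 (-0.28, SE 0.09), an antiproliferative gene. Camera gave an adjusted p of 0.00144 for that list, and adjusted p = 0.896 with an estimated correlation. It was 0.0548 after the GC offset and 0.541 without the 3 farthest libraries, and the list lost its call without glutamate replicate 4 (median -0.041), zinc replicate 4 (-0.090) or zinc replicate 5 (-0.062).

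The other early genes had log2 fold changes between zinc and glutamate alone of -0.16 (SE 0.19) for Fos, -0.17 (SE 0.11) for Egr1, -0.23 (SE 0.12) for Arc, -0.31 (SE 0.16) for Npas4 and -0.12 (SE 0.19) for Nr4a1, and of 0.09 (SE 0.13) for Bdnf. Some changed sign in other fits, Fos to 0.075 and Nr4a1 to 0.046 without the libraries picked by eye, and Egr1 to 0.0033 without the 3 farthest. Over single omissions Nr4a1 ran from -0.27 to 0.0041 and Bdnf from -0.029 to 0.17. Mt1 had 59.6 ± 5.39 CPM with zinc and 54.5 ± 3.24 without (0.13, SE 0.06, adjusted p = 0.785), and Mt2 35.9 ± 4.11 against 31.9 ± 2.96 CPM (0.17, SE 0.08, adjusted p = 0.832). Slc30a1 had -0.05 (SE 0.06) and Slc39a10 0.02 (SE 0.07). Of the 10 nuclear-retained long RNAs 9 had negative fold changes (median -0.13), 0 fell over all genes, and 3 fell adjusted over the list alone, namely Miat (-0.45, SE 0.11), Neat1 (-0.69, SE 0.20) and Snhg11 (-0.27, SE 0.10). That list's camera adjusted p was 0.00144. Heat shock and unfolded protein response genes had a median of 0.08 (21 of 23 positive, camera adjusted p = 0.00733), with the cytosolic chaperone Hsp90aa1 at 0.11 (SE 0.03) and the co-chaperone Dnaja1 at 0.12 (SE 0.05). Medians were 0.05 for ribosomal proteins (camera adjusted p = 9.06e-05), 0.02 for oxidative phosphorylation genes (0.0316) and -0.04 for voltage-gated potassium channels (0.0311). Without glutamate replicate 3 the first pair of these medians turned to -0.0047 and -0.0095. In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. For all 5 lists of this paragraph adjusted p = 0.896 with an estimated correlation. Of 10 single omissions, 1 ended the call of the nuclear RNAs (zinc replicate 4, median -0.095), 2 that of the ribosomal proteins (glutamate 3 and zinc 4), 3 that of the heat shock list (glutamate 5, zinc 1 and zinc 2, medians 0.015, 0.052 and 0.014), 6 that of the potassium channels (glutamate and zinc 1 and 2, glutamate 3, zinc 4) and 7 that of the oxidative phosphorylation genes (glutamate 1 to 3, zinc 1 to 4).

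The count of 0 came from edgeR, with 862 genes at an unadjusted p under 0.05 (721 by chance), while limma-voom called 0 and DESeq2 1. The authors' deposited table lists 1 gene at the same threshold. Without glutamate replicate 2 the count was 3, without zinc replicate 4 it was 2, without the 3 farthest libraries 1, without 3 libraries picked by eye 27, and with library weights in limma-voom 107.

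With the chelator TPA, again no gene passed the threshold against glutamate alone. The smallest p-values belonged to Ypel1, a member of the Yippee family, at 112 ± 2.60 CPM with TPA and 97.2 ± 6.24 without (n = 5 each; log2 fold change 0.21, SE 0.04, adjusted p = 0.516), to the interleukin-1 receptor accessory gene Il1rap (0.30, SE 0.07, adjusted p = 0.516), and to the semaphorin receptor subunit Plxna3 (0.18, SE 0.04, adjusted p = 0.516). The rapid immediate early genes lay on both sides of 0 (13 positive, 10 negative, median 0.05, camera adjusted p = 0.476), with 0 past the threshold over all genes and 0 adjusted over the list alone. Egr1 had 0.30 (SE 0.11), Egr2 0.41 (SE 0.14) and the small Maf factor Maff -0.81 (SE 0.24), while Fos had 0.03 (SE 0.19), Arc 0.10 (SE 0.12), Npas4 0.28 (SE 0.16) and Nr4a1 -0.08 (SE 0.19).

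Delayed activity-regulated genes had a median of -0.17 with TPA against glutamate (25 of 31 negative, camera adjusted p = 8.3e-06). None fell over all genes, and adjusted over the list alone 1 fell, the clock gene Per2 (-0.25, SE 0.06). Neuritin (Nrn1) had -0.17 (SE 0.06) and Bdnf -0.28 (SE 0.13). Heat shock and unfolded protein response genes had a median of -0.17 (18 of 23 negative, camera adjusted p = 0.000144), with Pdia4 at -0.28 (SE 0.09) and the endoplasmic reticulum chaperone Hsp90b1 at -0.21 (SE 0.08). Positive medians were measured for voltage-gated calcium channels and CaM kinases (0.06, camera adjusted p = 0.0164, with the channel subunit Cacnb3 at 0.14, SE 0.05), clustered protocadherins (0.05, 0.00164) and ribosomal proteins (0.04, 0.00164, but a median of -0.012 without glutamate replicate 3). In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. For all 5 lists adjusted p = 0.877 with an estimated correlation. The calcium channel list lost its call without glutamate replicate 4, TPA replicate 2 or TPA replicate 5 (medians 0.030, 0.045 and 0.036), the protocadherins without glutamate replicate 4 (0.025), and the ribosomal proteins without glutamate replicate 3, TPA replicate 1 (0.0075) or TPA replicate 3 (0.024). Mt1 had -0.07 (SE 0.06), Mt2 -0.19 (SE 0.08), Slc30a1 -0.11 (SE 0.06) and Slc39a10 0.09 (SE 0.07).

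The count of 0 came from edgeR, with 1030 genes at an unadjusted p under 0.05 (721 by chance). limma-voom called 0 and DESeq2 1, and the authors' deposited table lists 1 gene, Ypel1, with a log2 fold change of 0.18 and an adjusted p of 0.0111. The count was 1 without glutamate replicate 4, 2 without glutamate replicate 5, 551 without the 3 farthest libraries, 2 without 3 libraries picked by eye and 484 with library weights in limma-voom.

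Across the 14411 genes, the log2 fold changes of zinc and of TPA against the shared glutamate libraries had a correlation of 0.32 and a covariance of 0.00603 (across genes, which are not independent replicates). Unchanged groups drawn 100 times against the same libraries gave a mean correlation of 0.44, from -0.46 to 0.89, and a mean covariance of 0.00898. With the glutamate libraries split between the contrasts, the mean over 20 splits was -0.14 for the correlation and -0.00464 for the covariance. No gene passed the threshold in either contrast, so there was no overlap of calls to report.

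Genes that rose when 3 glutamate libraries were compared with control were read in the other 2 glutamate libraries. Over 10 such splits 2 to 14 genes rose. In the libraries not used for choosing, their median log2 difference from control was 1.23 (from -0.07 to 1.48 over the splits). Against those same libraries the median was -0.44 with zinc (from -0.72 to 0.19) and 0.05 with TPA (from -0.19 to 0.36). The zinc value was negative in 9 of the 10 splits. The exception had glutamate replicates 4 and 5 left for reading, and there the median of the chosen genes lay below control (-0.07). The TPA value was positive in 6 of 10. Fosb and Klf4 were chosen in all 10 splits and made up the whole set in 4, so these medians largely repeat 2 genes. Where 4, 9 and 14 genes were chosen, the zinc value was -0.05, -0.03 and 0.19. Genes fell against control in 1 split alone, that with replicates 4 and 5 left for reading, where 9 fell (median of -0.06 from control in the libraries left, -0.14 with zinc and -0.03 with TPA against them). These are values without a test of their own. All 5 control libraries served both for choosing the genes and for the difference from control, which may enlarge that difference.

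The comparison of chelated with added zinc during the glutamate pulse gave 51 genes higher and 23 lower with TPA than with ZnCl2. Miat, a long noncoding RNA kept in the nucleus, was 1.58-fold higher (154 ± 20.8 against 97.5 ± 7.98 CPM, n = 5 each; log2 fold change 0.66, SE 0.11, edgeR adjusted p = 0.0175). Flna, which encodes the actin crosslinker filamin A, was 1.37-fold higher (238 ± 19.9 against 174 ± 11.3 CPM; 0.45, SE 0.07, adjusted p = 0.0112), and Fblim1, whose product binds filamin, 1.38-fold higher (0.46, SE 0.10, adjusted p = 0.0363). Klf4 was 1.88-fold higher (2.29 ± 0.138 against 1.22 ± 0.304 CPM; 0.91, SE 0.17, adjusted p = 0.0199). Hmgb2, a chromatin protein gene, was 1.71-fold lower (2.52 ± 0.297 against 4.30 ± 0.353 CPM; -0.77, SE 0.12, adjusted p = 0.0096). For these 5 genes the 2 groups of libraries did not overlap.

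Among genes with a mean of at least 1 CPM and an established symbol, the next largest rises with TPA over zinc were the inactive rhomboid gene Rhbdf1 and the immunoglobulin superfamily gene Igsf9 (both 0.45), Lrrc45 (0.39), the cadherin gene Cdh24 (0.38), the orphan nuclear receptor gene Nr2f6 (0.36) and the kinesin gene Kif26a (0.36), with SE from 0.07 to 0.10. The largest rise past the threshold, 1.34, belonged to a gene outside that rule. Lower genes included Fam111a (-0.52, SE 0.12) and the spindle protein gene Nusap1 (-0.50, SE 0.10), both under 3 CPM, and Cacng3 (-0.34, SE 0.06), whose product is an auxiliary subunit of AMPA receptors. They also included Klhl13 (-0.30), Ccdc55 (-0.29), Tspyl2 (-0.27), the ribosome biogenesis gene Noc3l (-0.26), Lix1 (-0.26) and the RNA helicase gene Ddx10 (-0.24), with SE from 0.05 to 0.07. The respiratory complex III subunit Uqcrb also fell (-0.22, SE 0.05, adjusted p = 0.0416). Across the 74 genes the median log2 fold change was 0.25 for those that rose and -0.24 for those that fell.

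The list of metallothioneins and targets of the zinc-sensing factor MTF1 also includes the Mtf1 gene itself. Of its 9 tested members 7 were lower with TPA than with zinc. Over all genes 0 fell, and adjusted over the list alone 3 fell. Mt2 had 27.9 ± 3.47 CPM with TPA and 35.9 ± 4.11 with zinc (-0.36, SE 0.08, adjusted p = 0.0541), Mt1 51.9 ± 3.63 against 59.6 ± 5.39 CPM (-0.20, SE 0.06, adjusted p = 0.098), and the haem oxygenase gene Hmox1 -0.51 (SE 0.17, adjusted p = 0.15). In the authors' deposited DESeq2 table Mt2 (adjusted p = 0.00453) and Mt1 (0.0396) passed over all genes and Hmox1 (0.0539) did not. The list's camera adjusted p was 0.0468, and adjusted p = 0.526 with an estimated correlation. It lost its call in 6 of 10 single omissions (zinc replicates 1 to 4, TPA replicates 2 and 5; medians from -0.090 to -0.055). Slc30a1 had -0.06 (SE 0.06) and Slc39a10 0.07 (SE 0.07).

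Heat shock and unfolded protein response genes had negative fold changes in 22 of 23 cases (median -0.22, camera adjusted p = 2.45e-07, and adjusted p = 0.526 with an estimated correlation). None fell over all genes, and adjusted over the list alone 6 fell, among them Hsp90b1 (430 ± 27.7 against 541 ± 63.1 CPM; -0.33, SE 0.08), Pdia4 (-0.34, SE 0.09), the co-chaperone Dnajb9 (-0.45, SE 0.12) and the transcription factor Xbp1 (-0.18, SE 0.05). Rapid immediate early genes had 17 positive and 6 negative fold changes (median 0.14), with 1 that rose over all genes (Klf4). Adjusted over the list alone 10 rose and 3 fell. The higher ones included Egr2 (0.62, SE 0.15, adjusted p over all genes 0.0564), Egr1 (0.47, SE 0.11, 0.0592), the matricellular gene Cyr61 (0.75, SE 0.19, 0.0748) and Npas4 (0.59, SE 0.16, 0.0864). The 3 that fell were Atf3, a stress-responsive transcription factor, Maff and Arf4, a small GTPase gene, named after their values were seen. The camera adjusted p was 0.00257, and adjusted p = 0.684 with an estimated correlation. It was 0.121 after the GC offset, 0.0639 without the 3 farthest libraries, 0.0748 without zinc replicate 4 and 0.0797 without zinc replicate 5. Arc had 0.33 (SE 0.12), Fos 0.19 (SE 0.19) and Nr4a1 0.04 (SE 0.19). Hsp90b1, Pdia4, Dnajb9, Xbp1, Egr1, Egr2, Cyr61 and Npas4 passed over all genes in the authors' deposited DESeq2 table (adjusted p from 0.00278 to 0.0281). Arc, Fos and Nr4a1 did not pass there.

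Delayed activity-regulated genes had a median of -0.20 between TPA and zinc (25 of 31 negative, camera adjusted p = 0.000321, and adjusted p = 0.76 with an estimated correlation). None passed over all genes, and adjusted over the list alone 1 rose and 3 fell, including Nrn1 (-0.23, SE 0.06) and Per2 (-0.20, SE 0.06), while Bdnf had -0.37 (SE 0.13). Nrn1 passed over all genes in the authors' deposited DESeq2 table (adjusted p = 0.0188), and Per2 (0.0502) and Bdnf (0.0522) did not. Voltage-gated calcium channels and CaM kinases had a median of 0.07 (20 of 25 positive, camera adjusted p = 0.00117), with 0 past the threshold over all genes and, adjusted over the list alone, 6 that rose and 1 that fell, Camkk2 (0.33, SE 0.10) and Cacnb3 (0.20, SE 0.06) among the former. Glutamate receptors had a median of 0.05 with 0 over all genes and 3 that rose adjusted over the list alone. Nuclear-retained RNAs had a median of 0.13, with Miat past the threshold over all genes and both Miat and Snhg11 (0.29, SE 0.10) adjusted over the list alone. Clustered protocadherins had a median of 0.05 with 0 on either count. These last 3 lists shared a camera adjusted p of 0.0468. For the lists of calcium channels, glutamate receptors and nuclear RNAs adjusted p = 0.684 with an estimated correlation, and for protocadherins adjusted p = 0.9 with an estimated correlation. Glutamate receptors and protocadherins each lost their call without zinc replicates 1, 2 or 3 or TPA replicates 2, 4 or 5 (medians down to 0.016 and 0.024), and nuclear RNAs without zinc replicate 4 (0.055), TPA replicate 2 (0.12) or TPA replicate 5 (0.056). The calcium channel list kept its call in all 10 omissions, with medians from 0.053 to 0.14. Camkk2 (adjusted p = 0.0308) and Cacnb3 (0.0290) passed over all genes in the authors' deposited DESeq2 table.

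The 74 genes came with 2312 at an unadjusted p under 0.05 (721 by chance). limma-voom called 63 and DESeq2 481, and the authors' deposited table lists 456, which include 73 of the 74. Leaving out zinc replicates 1 to 5 in turn gave 24, 14, 5, 899 and 230 genes, and leaving out TPA replicates 1 to 5 gave 127, 16, 39, 31 and 15. Zinc replicate 4 was the only zinc library with a positive correlation with transcript GC content (r = 0.26). The count was 1149 without the 3 farthest libraries, 1310 without 3 libraries picked by eye, 3131 with library weights in limma-voom, 20 after the GC offset, 6 in a fit of the 2 groups alone, 37 with library sizes alone and 41 with no low-count filter. With the replicate number as a block, a planned choice, it was 422, and 267 with the GC offset too. Fold changes correlated with transcript GC content (r = 0.24 across genes, which are not independent replicates). The median GC was 56.5% for genes that rose, 43.1% for those that fell and 49.7% for all genes. This trend was not confined to TPA against zinc. Against glutamate alone r was -0.18 with zinc and 0.10 with TPA. Against control it was -0.16 with zinc, 0.12 with TPA and 0.0064 with glutamate alone.

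**Figure D2:**
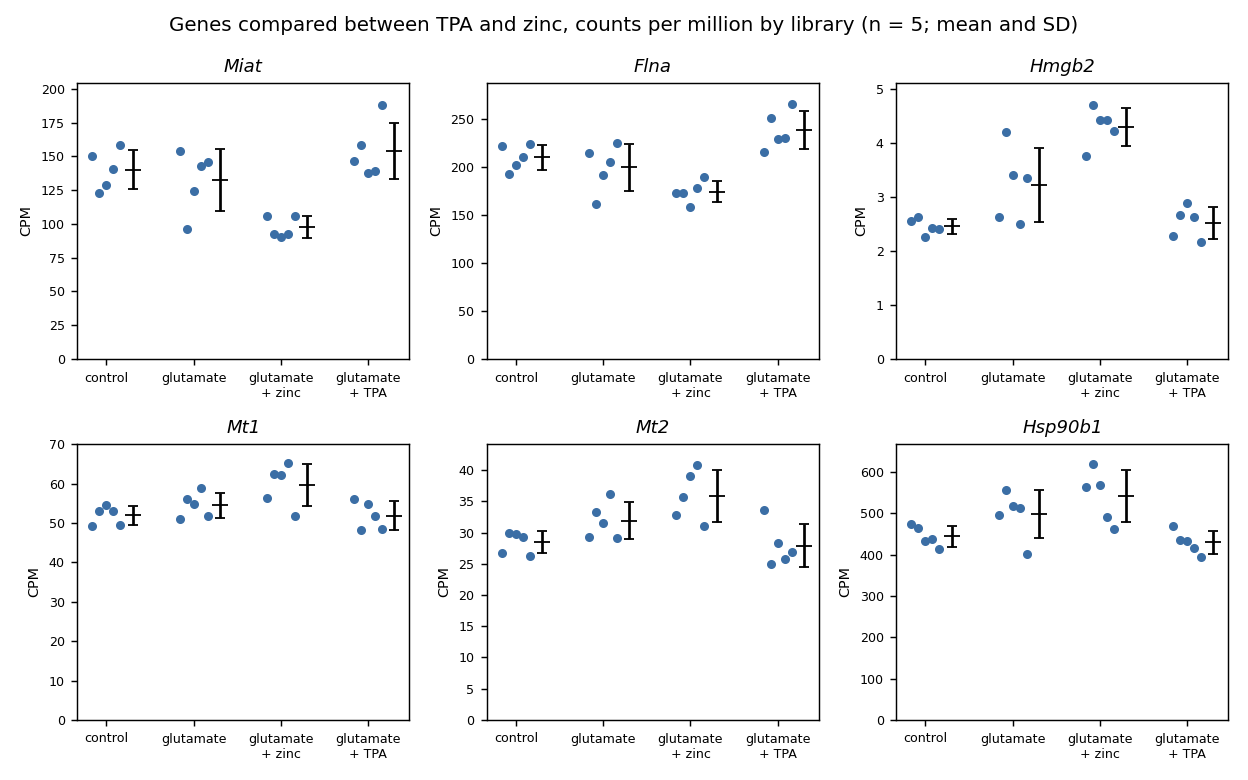
CPM of Miat, Flna, Hmgb2, Mt1, Mt2 and Hsp90b1 in each library of the 4 groups (points, n = 5 per group), with the mean and SD as a bar. Miat averaged 97.5 CPM with zinc and 154 CPM with TPA, and Hmgb2 4.30 CPM with zinc and 2.52 CPM with TPA.

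Against control, glutamate with zinc raised Nfkbiz 1.83-fold (2.99 ± 0.195 against 1.63 ± 0.119 CPM, n = 5 each; log2 fold change 0.87, SE 0.10, edgeR adjusted p = 7.72e-05), Fosb 1.78-fold (0.83, SE 0.12, adjusted p = 0.00304) and Hmgb2 1.75-fold (4.30 ± 0.353 against 2.45 ± 0.141 CPM; 0.81, SE 0.12, adjusted p = 0.00304). Plxna3 fell (-0.22, SE 0.04, adjusted p = 0.0418), as did Slc7a4, a member of an amino acid transporter family (-0.22, SE 0.04, adjusted p = 0.0151), and a tubulin pseudogene named after its value was seen, Tubb2a-ps2 (-0.37), whose reads may be shared with its parent gene. Of the rapid immediate early genes 21 of 23 had positive fold changes (median 0.30), with 1 that rose over all genes (Fosb) and 10 adjusted over the list alone, among them Klf4 (0.77, SE 0.20), Fos (0.96, SE 0.19) and Jun (0.23, SE 0.05). The camera adjusted p was 2.32e-11, and adjusted p = 0.275 with an estimated correlation. Egr1 had 0.22 (SE 0.11), Arc 0.11 (SE 0.13), Npas4 0.54 (SE 0.16), Nr4a1 0.45 (SE 0.19) and Bdnf 0.26 (SE 0.13). Fos (adjusted p = 0.00751) and Jun (0.0115) passed over all genes in the authors' deposited DESeq2 table, and Npas4 (0.207) did not.

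With zinc, Mt2 had 35.9 ± 4.11 CPM against 28.4 ± 1.77 in control (0.34, SE 0.08, adjusted p = 0.173) and Mt1 59.6 ± 5.39 against 52.0 ± 2.37 CPM (0.20, SE 0.06, adjusted p = 0.252). They were the 2 of 9 members of the metallothionein list that rose adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.152). Mt2 passed over all genes in the authors' deposited DESeq2 table (adjusted p = 0.0219), and Mt1 did not (0.0991). Slc30a1 had 0.04 (SE 0.06) and Slc39a10 -0.11 (SE 0.06). Heat shock and unfolded protein response genes had a median of 0.17 (21 of 23 positive, camera adjusted p = 8.01e-07, and adjusted p = 0.478 with an estimated correlation), 0 over all genes and 2 adjusted over the list alone, Hsp90b1 (0.29, SE 0.08) and Xbp1 (0.17, SE 0.05). Delayed activity-regulated genes had a median of 0.12 (30 of 31 positive, camera adjusted p = 2.58e-05, and adjusted p = 0.622 with an estimated correlation) with 0 on either count. Over single omissions that median ran from 0.088 to 0.19, and the list kept its call. Medians below 0 were measured for potassium channels (-0.07, camera adjusted p = 0.00827, 0 over all genes and 1 that fell adjusted over the list alone), calcium channels and CaM kinases (-0.06, 0.00359), glutamate receptors (-0.05, 0.03) and protocadherins (-0.04, 0.0256), the last 3 with 0 on either count. With an estimated correlation the adjusted p of these 4 lists ran from adjusted p = 0.556 to adjusted p = 0.793. Without zinc replicate 1 all 4 lost their call (medians -0.053, -0.038, -0.017 and -0.023), and glutamate receptors and protocadherins also did without zinc replicate 2 or 3 or control replicate 3.

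In this comparison 3 genes rose and 3 fell, with 1593 at an unadjusted p under 0.05 (721 by chance), 8 called by limma-voom and 61 by DESeq2. The authors' deposited table lists 59, of which 4 are among the 6. Nfkbiz and Hmgb2 had log2 fold changes of 0.41 and 0.38 there but no adjusted p, so that table gives no call for them. With library sizes alone 3 rose and 1 fell. The count was 100 without zinc replicate 4, 3 without zinc replicate 3, 3 without control replicate 1, 231 without the 3 farthest libraries, 521 without 3 libraries picked by eye and 1825 with library weights in limma-voom. With the planned block on the replicate number it was 39, and 69 with the GC offset too.

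Against control, glutamate with TPA raised 10 genes and lowered 0. The largest rises were Klf4 (3.20-fold; 2.29 ± 0.138 against 0.715 ± 0.132 CPM, n = 5 each; log2 fold change 1.68, SE 0.18, edgeR adjusted p = 2.86e-05), Cyr61 (2.76-fold; 9.69 ± 1.62 against 3.52 ± 0.762 CPM; 1.46, SE 0.20, adjusted p = 0.00188), Fos (2.22-fold; 77.8 ± 5.02 against 35.1 ± 4.32 CPM; 1.15, SE 0.19, adjusted p = 0.0213) and Fosb (2.22-fold; 1.15, SE 0.12, adjusted p = 2.86e-05). Npas4 rose 2.18-fold (63.1 ± 5.64 against 29.0 ± 3.00 CPM; adjusted p = 0.00457). Egr2 (1.02), the AP-1 subunit Junb (0.73), Egr1 (0.69), Nfkbiz (0.68) and Egr4 (0.43) rose by smaller amounts. For all 10 genes the libraries of the 2 groups did not overlap.

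All of these but Nfkbiz belong to the rapid immediate early list, of which 19 of 23 members had positive fold changes with TPA against control (median 0.37), 9 rose over all genes and 14 adjusted over the list alone. The camera adjusted p was 4.12e-37, and the list stayed past the threshold with adjusted p = 0.00179 with an estimated correlation. Arc had 0.44 (SE 0.12) and Nr4a1 0.49 (SE 0.19), neither past the threshold over all genes. Bdnf had -0.11 (SE 0.13), Mt1 -0.0011 (SE 0.06), Mt2 -0.02 (SE 0.08), Slc30a1 -0.02 (SE 0.06) and Slc39a10 -0.04 (SE 0.07). Oxidative phosphorylation genes had a median of -0.03 (66 of 88 negative, camera adjusted p = 0.000113, and adjusted p = 0.893 with an estimated correlation) with 0 on either count and Uqcrb at -0.14 (SE 0.05), and the list lost its call without TPA replicate 2 (median -0.0058). The 10 genes came with 446 at an unadjusted p under 0.05 (721 by chance), limma-voom and DESeq2 each called 10, and all 10 are in the authors' deposited table of 10. The count was 6 without control replicate 2 and 6 without TPA replicate 5.

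In the library and marker checks the smallest p that the exact test allows with 5 libraries per group is 0.00794, which for 1 comparison adjusts to 0.762 over the family of 96, so no comparison could pass by itself. That p was reached for markers of Cajal-Retzius cells, early-born neurons of the marginal zone, whose mean log2 CPM was 3.26 with TPA and 3.01 with zinc (difference 0.24, exact permutation p = 0.00794, adjusted p = 0.762). Markers of the oligodendrocyte lineage averaged 1.35 with zinc and 1.50 in control (difference -0.15, exact permutation p = 0.0476, adjusted p = 0.961).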

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

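The tests chosen only after a result was seen were those of GC content, other cell types and RNA quality for the TPA and zinc comparison, and those of depth and GC content for libraries far from their group. The splits of the samples were planned.

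In 188 groups of 5 values, 11 held a library whose gap to its nearest neighbour took an unusually large part of the range (above 0.71), where chance gives about 9.4. Glutamate replicate 4 stood apart 4 times, with 16996 genes detected against 17263 to 17354 in the others (gap ratio 0.746), and with the lowest means of the GABA receptor (0.718), voltage-gated potassium channel (0.759) and clustered protocadherin (0.776) lists. Glutamate replicate 5 had the lowest mean of the delayed activity-regulated genes (4.83 against 5.21 to 5.35 log2 CPM, gap ratio 0.741) and the lowest Bdnf (6.67 against 7.26 to 7.50 log2 CPM, 0.714). Zinc replicate 5 had the lowest means of the oxidative phosphorylation (0.767) and meningeal fibroblast marker (0.744) lists and the highest Slc39a10 (6.88 against 6.45 to 6.56 log2 CPM, 0.73). TPA replicate 1 had the lowest mean of the p53 and cell death list (0.771), and control replicate 5 the lowest mean of the oligodendrocyte markers (0.767).

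Of 100 splits of the 10 libraries, the real one included, 1 gave as many genes as glutamate against control (3 genes, highest other 0). For TPA against control it was also 1 of 100 (10 genes, highest other 0), and for zinc against control 2 of 100 (6 genes). Such counts were rare among the splits, which makes chance less likely in these comparisons without excluding it. Another split of the zinc and control libraries called 112 genes. For zinc against glutamate and TPA against glutamate the real count was 0, all 100 splits gave as many, and the highest others were 1172 and 485. For TPA against zinc 5 of 100 splits gave 74 genes or more, with 451 the highest, so chance cannot be excluded for that count. The highest other splits of TPA against zinc and of zinc against control exchanged 1 library per arm, so they still hold much of the group contrast. Those of the comparisons with glutamate alone exchanged 2 per arm, which points to a structure among the samples that the groups do not hold.

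Among the 74 genes that differed between TPA and zinc, GC content was tested as a technical source. After the GC offset these genes retained 85.6% of their median log2 fold change (0.24 before, 0.21 after). The median SE was 0.049 before and 0.047 after, and all 74 kept their direction. They were chosen by their fold changes in these same libraries, so the part kept cannot decide how far GC content contributed. Just 19 of them stayed past the threshold. The fold change shrank in 67 of the 74, and 31 still had an unadjusted p at or under 0.000256, where the adjusted threshold lay before the offset. After the offset it lay at 6.93e-05. Other cell types may contribute to the genes higher with TPA and cannot be told apart from an effect on the neurons, because the highest marker list median, that of microglia (0.23, SE 0.14), lies close to the 0.25 of the genes themselves. The microglia markers were low, at a mean of -0.94 log2 CPM with TPA and -1.11 with zinc (exact permutation p = 0.706, adjusted p = 0.961). Similar fold changes therefore do not show that such cells supplied the RNA of these genes. Cajal-Retzius markers, which had the smallest p of the marker checks (exact permutation p = 0.00794, the lowest that the design allows, adjusted p = 0.762), had a median of 0.16 (SE 0.12). RNA quality cannot be told apart either, since nuclear-retained RNAs and ribosomal protein genes moved apart by 0.13 (SE 0.06). Miat belongs both to the nuclear-retained list and to the 74 genes, so this gap is not independent of them. The state of zinc during the pulse, which the groups name, stays open beside these and beside chance.

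Glutamate replicates 5 and 4 and zinc replicate 5 lay farthest from the means of their groups, at root mean square log2 distances of 0.311, 0.300 and 0.299, where the other 17 libraries had a median of 0.215 and reached 0.271. Taking out GC content left the smallest of the 3 at 0.292, above the other 17 (median 0.214, median absolute deviation 0.0164), which argues against GC content as the whole cause. The values argue against library depth too. Glutamate replicate 4 and zinc replicate 5 had totals within the range of the other 17, and the 2 libraries whose totals lay farther from the median total than any of the 3, TPA replicates 2 and 4 with 28692470 and 29623687 counts, had distances of 0.226 and 0.204 (median absolute deviation of the 17, 0.016). Glutamate replicate 5 was the deepest library at 40934630 counts, and the next deepest, control replicate 3 with 39765787, had a distance of 0.195. No biological explanation was tested, since the labels give these libraries no property of their own beyond a replicate number. All 3 carry the number 4 or 5, as does the next farthest, zinc replicate 4 (0.271). Replicates 4 and 5 of control (0.207 and 0.198) and of TPA (0.204 and 0.217) did not lie far from their groups. A link with the replicate number was not tested. Culture or handling differences within a group remain possible and untested.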

How the results depend on the processing

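The GC offset, library weights and fits without 3 libraries were chosen after seeing the data, and the other alternatives were planned. Causes were not tested unless given. Comparisons are in the order glutamate against control, zinc against glutamate, TPA against glutamate, TPA against zinc, zinc against control, TPA against control, with 3, 0, 0, 74, 6 and 10 genes.

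DESeq2 gave 14, 1, 1, 481 and 61 in the first 5. Without the 3 libraries farthest from their group the first 5 gave 100, 1, 551, 1149 and 231. Without 3 libraries picked by eye (glutamate 4, zinc 4, TPA 1), on a component that itself tracked TPA against zinc, they gave 5, 27, 2, 1310 and 521. These 3 had the highest correlations with transcript GC content of the 20 libraries (r = 0.21, 0.26 and 0.22). Zinc replicates 1, 2, 3 and 5 had r of -0.15, -0.10, -0.24 and -0.29, so without zinc 4 every zinc library was negative. Whether GC content raised the counts without zinc 4 was not tested. Library weights gave 59, 107, 484, 3131 and 1825. DESeq2's size factors and a minimum of 1 CPM each gave 5 for glutamate against control. TPA against zinc gave 37 with library sizes alone, 41 with no low-count filter, where more genes were tested, 6 in the fit of those 2 groups alone, which has fewer samples, and 20 after the GC offset. Counts for TPA against control stayed within 1.5 times of 10 in every fit that left out no single library.

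The replicate numbers were not taken to pair the libraries, since 11 of the 30 same-numbered pairs, not all, had deviations correlated above 0.1 (median 0.06, from -0.07 to 0.50), against 18 of 120 other pairs (median -0.02). Of 20 libraries 9 correlated best with their own number, where chance gives 4, a hint of a shared deviation. Pairing is therefore not excluded, and the main fit, the splits and the permutation tests left it out. With the number as a block the counts for TPA against zinc and zinc against control were 422 and 39. With the block and the GC offset they were 267 and 69, with 6 for glutamate against control and 1 for TPA against glutamate.

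Leaving out single libraries gave 2 to 5, 0 to 3, 0 to 2, 5 to 899, 3 to 100 and 6 to 10 genes. The rapid immediate early list lost its call with an estimated correlation in zinc against glutamate (median -0.12), TPA against zinc (0.14) and zinc against control (0.30). It lost it after the GC offset in the first of these (-0.10) and the second (0.13), and without the 3 farthest libraries in both (-0.0093 and 0.076). Single omissions moved its median from -0.25 to -0.041 in zinc against glutamate and from 0.076 to 0.17 in TPA against zinc, each losing some calls, and from 0.037 to 0.16 in TPA against glutamate, gaining 1. The correlation of zinc and TPA effects was 0.18 with a minimum of 1 CPM and -0.14 with split glutamate libraries. Medians of the glutamate-response genes moved by less than their spread.

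Of 3215 estimates of named genes under alternatives, 2788 stayed on their side of the threshold, 195 lost and 196 gained a call, and 36 changed sign, all of genes past it in no fit. For TPA against control Mt1 was 0.00063 with library sizes alone, 0.00022 with the block, 0.00017 in the fit of 2 groups and -0.029 to 0.024 over single omissions, Mt2 -0.10 to 0.015 over these, and Slc30a1 0.022 without the by-eye libraries, 0.0030 with library weights and -0.047 to 0.023 over omissions. For zinc against glutamate Slc39a10 was -0.0015 after the GC offset, -0.0046 with the block too, -0.042 without the farthest libraries, -0.032 with weights and -0.056 to 0.053 over omissions. There, Fos was 0.075 and Nr4a1 0.046 without the by-eye libraries, Egr1 0.0033 without the farthest, Nr4a1 -0.27 to 0.0041 and Bdnf -0.029 to 0.17 over omissions. For TPA against glutamate Fos was -0.00061 with weights and -0.093 to 0.16 over omissions, and Nr4a1 -0.23 to 0.021. For TPA against zinc Nr4a1 was -0.0043 after the GC offset, -0.083 without the by-eye or the farthest libraries, -0.12 with weights and -0.083 to 0.17 over omissions. No adjusted p or no test was had for 5 estimates.

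Of 480 estimates of called lists other than the rapid immediate early list, 373 kept and 102 lost their call. Without glutamate replicate 3, 5 medians changed sign, and single omissions moved the ribosomal list from -0.070 to 0.017, -0.0047 to 0.086 and -0.012 to 0.070 in the first 3 comparisons and the oxidative phosphorylation list from -0.055 to 0.0042 and -0.0095 to 0.051 in the first 2. Depth limits genes near 0.105 CPM, which is 3 counts in the smallest library.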

Other observations

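The list of serum response factor targets was drawn up only after the genes that differed between TPA and zinc had been seen. The held-back members were tested before their values were known.

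Some transporter and metabolic genes passed when adjusted over their own list and not over all genes. Slc17a6, which encodes a vesicular glutamate transporter, was -0.36 (SE 0.09) with TPA against zinc and 0.30 (SE 0.09) with zinc against control, and both passed when adjusted over the list alone (presynaptic vesicle genes), with adjusted p = 0.0583 and 0.217 over all genes in edgeR. With TPA against zinc Hk2, the hexokinase gene of glycolysis, was -0.58 (SE 0.15, adjusted p = 0.064) and Vegfa, an angiogenic growth factor gene, -0.16 (SE 0.04, adjusted p = 0.064), and both passed adjusted over the hypoxia and glycolysis list alone. These 3 were chosen after their values were seen. Across marker lists of other cell types, the median log2 fold change of TPA against zinc was 0.06 for astrocytes and radial glia, 0.07 for the oligodendrocyte lineage, 0.23 for microglia, 0.14 for endothelial cells and pericytes, 0.19 for choroid plexus and ependyma, -0.14 for meningeal fibroblasts and 0.16 for Cajal-Retzius cells, with SE of 0.05, 0.07, 0.14, 0.21, 0.19, 0.12 and 0.12.

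Flna, Fblim1 and Cyr61 are known targets of serum response factor (SRF), a transcription factor that couples actin dynamics to transcription, and it was asked whether SRF targets as a class may be higher with TPA than with zinc. Of 27 cytoskeletal SRF targets whose values had not been seen, 23 were tested, and 16 had positive fold changes with a median of 0.054 (SE 0.025). None passed the threshold, 0 passed adjusted over the list alone, and the list did not stand apart from other genes (camera p = 0.134, p = 0.237 with an estimated correlation, and p = 0.267 after the GC offset). After the GC offset the median over these genes was 0.037 with SE 0.034. The test gave no support for the hypothesis, and a small common shift cannot be told apart from none at this spread.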
